A study of Saccharomyces cerevisiae with 112 samples.

How the data were processed

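Genomic DNA or RNA of each strain and of a wt reference, labelled with Cy3 and Cy5, was hybridised together to 1 of 112 arrays. The strain was in Cy3 on 22 of the 44 DNA arrays and on 13 of the 14 chemostat disome arrays, and in Cy5 on all other RNA arrays. Groups, dyes and extra chromosomes were taken from the labels. For the DNA array of Dis II (A12685) the title and the source names put the strain in opposite channels, and the title was followed, with which chromosome II read 0.76. The wt reference strain was A11311, and the cdc mutants had their own wt, A2587. Batch disomes were measured against several wt reference RNAs, which were read from the labels. The main fits had no term for them. They were treated as batches only in an alternative with the reference RNA as a block and in values within 1 reference.

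Per the file headers, the scanned images were read with Agilent Feature Extraction, version 7.5.1 on 96 arrays, 8.1.1.1 on 8, 9.1.3.1 on 7 and 9.1.1.1 on 1. The deposited scanner files give, for each spot and channel, mean signal and local background as intensity, and a background-subtracted, dye-normalised processed signal as intensity. They also give log10 of red over green processed signal, per the file headers, dye-normalised within the array by a LOWESS curve on the 96 arrays of version 7.5.1 and linearly on the others, which are all DNA arrays. The authors' deposited series tables are in log2 of strain over wt, and they equal the scanner's log ratio turned by the dye orientation to within 5e-04. No genome build is given in the sources used here, so genes are placed by chromosome and order only. Of the 6256 genes, 5756 were matched by open reading frame name to the RefSeq gene list of this species and 500 were not.

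For RNA, mean signals were corrected for local background with the normexp method of limma 3.58.1 (offset 50), then normalised within each array by a loess curve (span 0.3) fitted to genes off the extra chromosome. For DNA, Agilent's processed signals were used and centred on each array's median, except that DNA of the brightness classes, of the gene for gene comparison with RNA and of HXT6 and HXT7 was taken from Agilent's log ratios, centred on the other genes of the class or on the array's median. Spots of a gene were averaged, and 5767 genes above background on a share of at least 0.5 of the RNA arrays were kept. All computations used R 4.3.3 with the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision.

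A chromosome was counted as gained when its median log2 exceeded 0.3, a threshold set before the data were examined, as were the groups, comparisons, gene lists, most of the alternatives and the rule for naming genes. Segments were searched with windows of 20 genes. Expression on the extra chromosome was the mean over its genes minus the median of all other genes. It was averaged per strain and tested over strains with an exact sign-flip test. Groups were compared with limma (lmFit, eBayes) at a Benjamini-Hochberg adjusted p under 0.05, with the strain as the replicate, so that 2 arrays of a strain were averaged first. A strain's own extra chromosome was set to missing, and a gene needed at least 10 strains. The 3 batch comparisons shared 1 fit. The chemostat comparisons and the batch against chemostat difference shared a joint fit of all RNA groups with a dye term for each gene, which the 4 batch wt arrays and the chemostat disomes inform. The cdc mutants were measured against their own wt, A2587. In batch their ratio was compared with that of the 4 A11311 wt against wt arrays, and in the chemostats it was tested against 0, so that the spread of A2587 is left out. Disome against cdc compares ratios to different references. The per-strain fit used 41 arrays and adjusted within each strain. Bounds for a gene not above background in a channel took the array's lowest signal above background in that channel.

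Each of 34 gene lists, those with at least 3 measured genes, was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and by an exact permutation test of the list mean per array, adjusted over lists within a comparison. Lists described in the report were chosen after their values were seen. Lists on the extra chromosome were tested by permuting genes within chromosomes (100000 permutations). Pearson and Spearman correlations had permutation p-values and were repeated without the 2 strains farthest from the median. All tests were two-sided. Genes were named by rule: up to 12 with the largest rise and up to 12 with the largest fall among those past the threshold, with the same sign in at least 80% of strains and a standard symbol. For a list, up to 2 members each way past the threshold were named, or otherwise the 2 largest differences, and on the extra chromosome the 5 lowest and 5 highest genes. PDR5, CLN2, HIS3, CDC15, CDC23 and CDC28 were always to be named.

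Alternatives changed 1 choice at a time, except that subtracting the dye effect of the wt arrays went with fitting the chemostat arrays alone. They covered the signal (Agilent's log ratios, the deposited values, no background subtraction), the normalisation, the filter, the genes on the extra chromosome, the strains with several extra chromosomes, blocks for platform, scan day, reference RNA and replicate, the dye term, and leaving out each replicate, mutant or wt array. With 100 drawn splits, or all where there were fewer, the samples were also divided into other groups of the same sizes. The fits were tested on simulated data, with 200 genes raised by 1 on the log2 scale in 5 simulations. They found 194 genes with 11.8 false ones for disome against wt in batch, 189 with 8.8 for the cdc mutants and 194 with 8.8 for disome against cdc. In the chemostats they found 184 with 11.8 for disome against YAC, 154 with 8.6 for disome against wt, 166 with 8 for YAC against wt and 191 with 10 for the cdc mutants, and for the batch against chemostat response 130 with 7.8. A chromosome raised by 0.58 or 1 was found in 100% of 100 simulations, with 0 false gains. Replicate arrays of a strain correlated across genes with r from 0.50 to 0.95 (median 0.86, 18 pairs), where genes are not independent replicates.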

Results

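The series examined what extra chromosomes do to gene dosage and gene expression in budding yeast, Saccharomyces cerevisiae. Disomes (Dis, followed by the chromosome) are haploid strains that carry an additional copy of 1 or more of their chromosomes, and each was compared with a euploid wild type (wt) on 112 2-colour oligonucleotide arrays of 6256 genes. Genomic DNA was measured on 44 arrays, 36 of disomes, 7 of strains labelled trisome and 1 of wt against itself. RNA of cultures growing in batch was measured on 44 arrays: 37 of 19 disome strains, 4 of wt against itself and 3 of the cell division cycle mutants cdc15-2, cdc23-1 and cdc28-4, which carry no extra chromosome. RNA of phosphate-limited chemostats, all run at a dilution of 0.17 volumes per hour, was measured on 24 arrays: 14 of disomes, 6 of strains with a yeast artificial chromosome (YAC), 1 of wt and 3 of the same cdc mutants. In batch 18 strains had 2 arrays and Dis V had 1, and no chemostat or mutant had a repeat. The share of genes above background was 85.9% to 95.7% on the batch arrays, 91.5% to 97.0% on the chemostat arrays and 99.8% to 100% on the DNA arrays, and the number of arrays limits the precision of every value. Values are log2 of strain over wt RNA or DNA, and SD and SE stand for standard deviation and standard error.

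The DNA arrays asked whether each strain held the chromosomes named in its label. All 49 labelled chromosomes were raised, and none of the 655 chromosomes outside the labels was. In disomes the labelled chromosome had a median log2 of 0.91 ± 0.11 (SD, 42 chromosome values on 36 arrays), or 1.87-fold, with a range of 0.55 to 1.10. Strains with a single labelled chromosome lay at 0.94 ± 0.07 (SD, 31 chromosome values), and strains with several at 0.80 ± 0.14 (SD, 11 chromosome values). The lowest values were those of Dis I, VI, and XIII, at 0.55, 0.57 and 0.74, and chromosome VIII of Dis VIII and XIV, at 0.68. Trisomes lay at 0.49 ± 0.04 (SD, 7 arrays), or 1.40-fold, below the disomes (exact permutation test, two-sided p = 3.1e-08). The labels do not give the ploidy of the trisomes, and on their arrays the reference's ADE1 signal was higher than on the others (a median of 34.7% of the array's median against 1.14%), so the copy number behind 1.40-fold is not settled. Chromosomes outside the labels had an SD of 0.04 and a range of -0.24 to 0.16, and a chromosome counted as raised above 0.3.

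**Figure D1:**
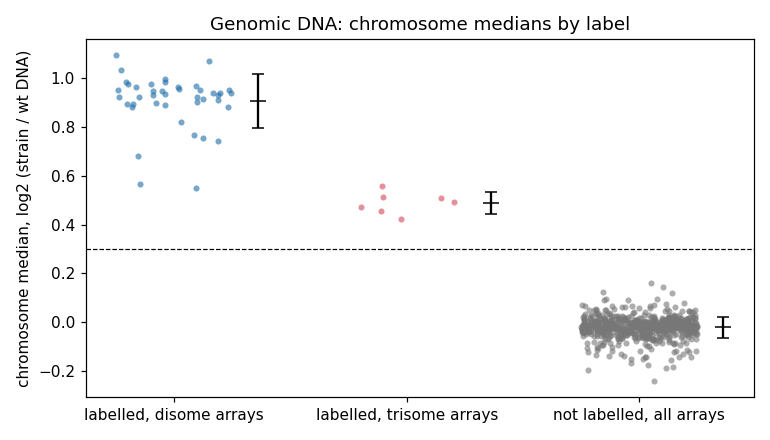
Median log2 of strain over wt DNA for each chromosome of each genomic DNA array, split into chromosomes the labels name in disomes, those they name in trisomes, and all others. Labelled chromosomes lie between 0.42 and 1.10 and the 655 others between -0.24 and 0.16.

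PDR5 (YOR153W, chromosome XV), a multidrug transporter, is named as deleted in the labels of 11 DNA arrays. On 6 of the 11 arrays its DNA log2 was low, between -7.27 and -4.55, with the 1 strain signal not above background set to the lowest that was. There the reference gave 12.3% to 90.9% of the array's median reference signal. On the other 5, the reference channel gave at most 0.188% of that median, so no ratio can be read. The 33 arrays without this label lay at 0.13 ± 0.28 (SD). The difference of the means of all 11 and these 33, -3.05 (exact permutation test, two-sided p = 8.8e-04), includes the ratios without reference signal and is no measure of the deletion. ADE1 (YAR015W, chromosome I), an enzyme of adenine synthesis, read 5.96 ± 1.06 (SD, 31 arrays) in disomes without an extra chromosome I, against a processed reference signal of 2.36 to 64.2 that was above background on 19 of the 31, so the size of this ratio is uncertain.

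Expression of genes on the extra chromosome was raised in every strain in both growth conditions. In batch it was 0.60 ± 0.06 above the other genes (SD, 19 strains), or 1.52-fold, with strain means from 0.46 to 0.73 (exact sign-flip test, two-sided p = 3.8e-06, the smallest it can give). In the chemostats it was 0.67 ± 0.05 (SD, 14 strains), or 1.59-fold, from 0.52 to 0.73 (exact sign-flip test, two-sided p = 1.2e-04, the smallest it can give). For the strains measured in both conditions, batch minus chemostat was -0.05 ± 0.03 (SD, 14 strains), with the chemostat higher in 12 (exact sign-flip test, two-sided p = 7.3e-04). That sign turned with Agilent's own log ratios, to 0.02. The strain was in Cy5 on every batch array and in Cy3 on 13 of the 14 chemostat arrays, so dye orientation went with growth condition. With the dye effect of the wt arrays subtracted the difference was -0.04 (exact sign-flip test, two-sided p = 6.1e-04). RNA lay below the DNA gain of the same strain in 19 of 19 batch strains, by a mean RNA minus DNA of -0.34 ± 0.11 (SD; exact sign-flip test, two-sided p = 3.8e-06). In the chemostats that difference was -0.27 ± 0.10 (SD, 14 strains; exact sign-flip test, two-sided p = 1.2e-04). The 2 sides were processed differently: RNA is a gene mean with the background model and its offset, and DNA a chromosome median of Agilent's processed signals. The size of the gap therefore depends on the processing. With Agilent's log ratios the brightest class of genes read 0.88 in batch RNA and 0.89 in DNA.

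**Figure D2:**
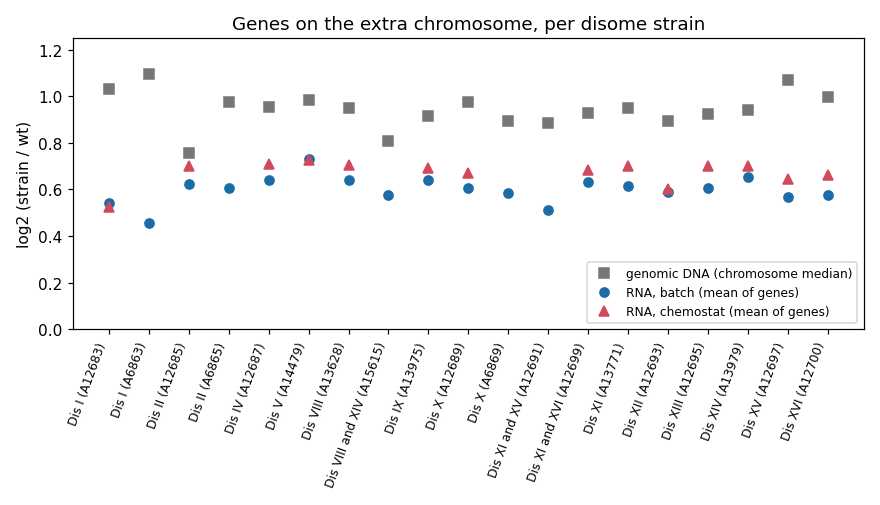
Log2 of the extra chromosome for each disome strain: mean of its genes in batch and chemostat RNA with the background model used here, and chromosome median in genomic DNA. Batch RNA lies between 0.46 and 0.73 and is below the DNA value in 19 of 19 strains.

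The RNA gain went with the brightness of the gene's spots. Over 4 equal classes of genes ordered from dim to bright, batch RNA on the extra chromosome rose from 0.29 through 0.57 and 0.72 to 0.83, while DNA of the same genes read 0.91, 0.93, 0.92 and 0.89. With Agilent's log ratios the RNA classes were 0.77, 0.90, 0.91 and 0.88. Of 4700 genes measured on an extra chromosome in at least 3 arrays, 97.4% had a mean above 0, 64.1% lay between 0.5 and 1.5, and 11.6% lay below 0.2.

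**Figure D3:**
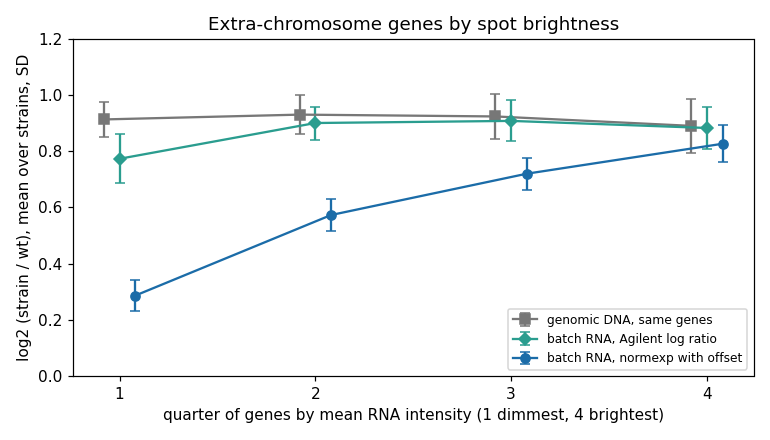
Mean log2 of genes on the extra chromosome by class of spot brightness (1 dimmest, 4 brightest), over 19 batch strains, for RNA with the background model used here, RNA with Agilent's log ratios, and DNA of the same genes. The first series climbs from 0.29 to 0.83, and DNA stays between 0.89 and 0.93.

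The lowest genes on an extra chromosome were biosynthetic genes whose DNA was low in the same strains, so their RNA is no measure of expression from 2 copies. In these strains DNA read -4.36 for URA5, at most -3.33 for URA2 and at most -4.07 for ADE16. URA5 (YML106W, pyrimidine synthesis) was at -5.49 ± 0.27 (SD, 3 arrays) in Dis XIII, URA2 (YJL130C, pyrimidine synthesis) at -5.25 ± 0.23 (SD, 5 arrays) in Dis X, and ADE16 (YLR028C, purine synthesis) at -3.24 ± 0.25 (SD, 3 arrays) in Dis XII. ADE16 signal was above background on none of these 3 arrays, so the fall has no exact size. For URA2 the strain signal was above background on 2 of the 4 batch arrays, so its fall has no exact size either. ZPS1 (-2.78 ± 2.46, SD, 5 arrays) and LEU9 (-2.01 ± 2.19, SD, 5 arrays) followed. The highest were HXT7 (5.34 ± 1.36, SD, 3 arrays) and HXT6 (5.11 ± 1.13, SD, 3 arrays), which encode high-affinity hexose transporters. They were followed by HSP31 (3.14 ± 1.60, SD, 3 arrays), the cell wall gene CIS3 (3.06 ± 0.39, SD, 5 arrays) and CPP3 (3.06 ± 1.89, SD, 3 arrays). In 18 strains without an extra chromosome IV, HXT6 and HXT7 already had a mean batch RNA of 2.65. Their values here are therefore no measure of expression from 2 copies alone.

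Some gene groups on the extra chromosome departed from their neighbours on the same chromosome (permutation over genes within chromosomes, two-sided, 32 lists per growth condition). In batch, 17 cell wall stress genes exceeded the other genes by 0.96 (adjusted permutation p = 8.0e-05), 65 environmental stress induced genes by 0.56 (adjusted permutation p = 8.0e-05) and 31 proteasome genes by 0.42 (adjusted permutation p = 9.1e-04). Cytosolic ribosomal protein genes (120) lay lower by -0.15 (adjusted permutation p = 0.0027), while 106 ribosome biogenesis genes were at -0.04 (adjusted permutation p = 0.38). In the chemostats ribosome biogenesis was at 0.53 and stress induced genes at -0.34 (adjusted permutation p = 1.6e-04 each), ribosomal proteins at 0.18 (adjusted permutation p = 4.3e-04), proteasome at 0.27 (adjusted permutation p = 0.0080) and cell wall genes at 0.28 (adjusted permutation p = 0.053). The purine and pyrimidine synthesis list was at -0.53 in batch (31 genes, adjusted permutation p = 8.0e-05) and -0.33 in the chemostats (adjusted permutation p = 0.0047), but these values rest on URA5, URA2 and ADE16: without them it was at -0.02 in batch (adjusted permutation p = 0.81) and at 0.21 in the chemostats (adjusted permutation p = 0.029). In all, 15 lists passed in batch and 8 in the chemostats, where 4 passed with Agilent's log ratios. The permutation treats genes as independent and leaves out the spread over strains, so genes that vary together can make these p-values too small. Values on the extra chromosome also rose with spot brightness, from 0.29 to 0.83 in batch, and the lists were not matched for it. With each gene's mean in the disomes that do not carry it subtracted, 3 values named here turned sign: ribosomal proteins in batch came to 0.02 (adjusted permutation p = 0.60), ribosome biogenesis in batch to 0.11 (adjusted permutation p = 0.023) and stress induced genes in the chemostats to 0.19 (adjusted permutation p = 0.0052). So did the phosphate regulon in batch, from -0.20 (adjusted permutation p = 0.082) to 0.30 (adjusted permutation p = 0.023), and lists that passed in neither setting. Chemostat ribosomal proteins then no longer passed, at 0.01 (adjusted permutation p = 0.86), chemostat ribosome biogenesis fell to 0.17 (adjusted permutation p = 6.4e-04), and batch stress induced genes to 0.26 (adjusted permutation p = 3.2e-04) and proteasome genes to 0.26 (adjusted permutation p = 0.013).

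Disomes were set against wt in batch to find expression changes away from the extra chromosome, whose own genes were left out of each strain. ADE1 rose by 3.19 ± 0.25 (SE, 17 of 17 strains; adjusted p = 3.3e-08) and LYS2 (YBR115C, chromosome II), an enzyme of lysine synthesis, by 2.43 ± 0.22 (SE, 17 of 17 strains; adjusted p = 3.5e-07). ADE1 signal in the wt reference was near background, so its fold is a lower bound, at least 75.8-fold as the mean over 17 strains. ADE1 DNA was also low in the reference strain, so its rise cannot be read as a response to the extra chromosomes. For LYS2 the median signal was 289 in the disomes' references and 3760 in that of the cdc mutants. A trait of the wt strain A11311 was thus not separated from a response of LYS2. No other gene of 5767 passed, and 382 had an unadjusted limma p under 0.05 where 288 are expected by chance. The hexose transporter genes HXT7, at 2.66 ± 0.76, and HXT6, at 2.42 ± 0.70 (SE, higher in 17 of 18 strains each), had an adjusted p of 0.71.

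Of 33 gene lists, 16 passed in this comparison with a preset correlation, 11 higher and 5 lower, and none with an estimated correlation. The proteasome list was higher in 40 of 42 genes (mean 0.13, adjusted p = 7.7e-10, adjusted p = 0.67 with an estimated correlation), among them SEM1 (0.29 ± 0.11, SE) and RPN4, the transcription factor of proteasome genes (0.25 ± 0.13, SE). Oxidative phosphorylation had 35 of 35 genes higher (mean 0.26, adjusted p = 6.7e-07, adjusted p = 0.72 with an estimated correlation), with NDE1 at 0.66 ± 0.33 and COX7 at 0.40 ± 0.21 (SE). Environmental stress induced genes were higher in 70 of 77 cases (mean 0.25, adjusted p = 1.4e-05, adjusted p = 0.72 with an estimated correlation), with CRG1 at 0.76 ± 0.32 and TMA10 at 0.72 ± 0.42 (SE). The cell wall stress list was higher in 16 of 19 genes (mean 0.38, adjusted p = 1.4e-05, adjusted p = 0.67 with an estimated correlation), with GSC2, a glucan synthase subunit, at 0.98 ± 0.45 and PIR3 at 0.87 ± 0.57 (SE). Hexose transporters were higher in 9 of 12 (mean 0.46, adjusted p = 0.021, adjusted p = 0.67 with an estimated correlation). The phosphate regulon was lower in 21 of 26 genes (mean -0.38, adjusted p = 1.7e-04, adjusted p = 0.72 with an estimated correlation), with the acid phosphatase gene PHO5 at -1.37 ± 0.63 and SPL2 at -1.19 ± 0.56 (SE). Ribosome biogenesis was lower in 89 of 123 genes (mean -0.06, adjusted p = 0.0018, adjusted p = 0.83 with an estimated correlation), with KRE33 at -0.31 ± 0.14 and LOC1 at 0.30 ± 0.21 (SE).

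Adjusted over the list alone, 6 genes in all passed, 2 of them in the cell wall list and 2 among hexose transporters, against 2 over all genes. When each array's list mean was compared by permutation, no list passed after adjustment: cell wall stress had permutation p = 0.015 (adjusted 0.25), hexose transporters permutation p = 0.012 (adjusted 0.25) and proteasome permutation p = 0.030 (adjusted 0.29), all two-sided. Among strains measured against the first wt reference RNA (3 strains, 1 wt array) and those against the second (11 strains, 2 wt arrays), ADE1 and LYS2 were at 3.11 and 2.33 in the second and not tested in the first. The list means in these batches were 0.12 and 0.12 for proteasome, 0.24 and 0.21 for stress induced genes, 0.20 and 0.41 for oxidative phosphorylation, 0.41 and 0.50 for cell wall stress, and 0.43 and 0.46 for hexose transporters. The phosphate regulon was at -0.19 and -0.50 in these batches, and ribosome biogenesis at -0.22 and 0.17. Ribosome biogenesis also turned to 0.01 without wt replicate 1, to 0.02 without wt replicate 4 and to 0.05 with the reference RNA as a block. Fitted on all arrays with the replicate number as a block, the comparison called the same 2 genes (shared 2).

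The cdc mutants were set against their own wt, A2587, to describe cell cycle mutants without an extra chromosome. Batch values are the ratio of mutant to A2587 minus the ratio on the 4 arrays of the other wt, A11311, against itself, which takes out the dye effect. Over the 3 mutants in batch, 84 genes rose and 145 fell of 5767. The 12 largest rises ran from HPF1 (YOL155C), a cell wall mannoprotein gene, at 2.18 ± 0.51 (SE, adjusted p = 0.024), through ATG39 at 0.92, CIR1 at 0.90, COX20 at 0.83, AIM41 at 0.80, CCC1 and FIS1 at 0.77, RBK1 at 0.72, ORA1 at 0.71, MGM101 at 0.67 and MIC27 at 0.66, to GID8 at 0.64. The 12 largest falls were FRE4 at -0.96, PLB2 at -0.92, SRO9 at -0.89 ± 0.17 (SE, adjusted p = 0.0092), SRP40 at -0.83, EUG1 at -0.79, RSA4 at -0.65, ARX1 at -0.64, HMS2 at -0.62, ARE2 at -0.60, VTS1 at -0.59, DNF2 at -0.58 and SAT4 at -0.57. RSA4 and ARX1 act in ribosome assembly. All 24 had their direction in 3 of 3 mutants.

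By list, oxidative phosphorylation was higher in 35 of 35 genes of the cdc mutants (mean 0.74, adjusted p = 5.5e-12, adjusted p = 0.82 with an estimated correlation), with CYC1 at 1.02 ± 0.48 and ATP7 at 0.99 ± 0.30 (SE). Stress induced genes were higher in 74 of 77 (mean 0.68, adjusted p = 2.5e-09, adjusted p = 0.82 with an estimated correlation), with OM45 at 1.51 ± 0.50 and TMA10 at 1.46 ± 0.57 (SE), and mitochondrial ribosome genes in 66 of 71 (mean 0.28, adjusted p = 5.9e-07, adjusted p = 0.82 with an estimated correlation). Ribosome biogenesis was lower in 94 of 123 (mean -0.15, adjusted p = 1.7e-05, adjusted p = 0.82 with an estimated correlation), and its members ARX1 (-0.64 ± 0.16, SE) and UTP5 (-0.53 ± 0.15, SE) fell. In all 10 of 33 lists passed with the preset correlation, and 59 genes passed when adjusted over the list alone, 31 of them in oxidative phosphorylation. The smallest permutation p that 3 arrays against 4 allow is 0.029. The 3 mutants shared a scan day and a reference that no batch array of wt or disomes had, so these cannot be told apart from the mutations. The count of 229 rests on single arrays: it was 1103 without cdc15-2, 1 without cdc23-1, 2 without cdc28-4, 73 without wt replicate 2 and 20 without wt replicate 3. It fell to 76 with Agilent's log ratios, to 4 with genes on the extra chromosome kept, and to 0 in limma (507 unadjusted) with all arrays and the strain as a random block.

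Disomes against cdc mutants asked which changes differed between the 2 kinds of strain. Each value is a difference of ratios to different wt references, A11311 for disomes and A2587 for the mutants. In all, 122 genes were higher and 89 lower. The ratio of ADE1 (2.61) and of LYS2 (2.01) was higher in disomes in 17 of 17 strains each, and it followed the references: the median LYS2 signal was 4086 in disomes and 3722 in the mutants, but 289 and 3760 in their references, and that of ADE1 was 38.8 in the disomes' reference and 1375 in the mutants'. The following genes were lower in disomes than in the mutants: ARG1 (YOL058W) by -1.83 ± 0.43 (SE, adjusted p = 0.022), ARG3 (YJL088W) by -1.48 ± 0.28 (SE, adjusted p = 0.0065), ARG56 by -1.18, ARG8 by -0.65, ADE17 (YMR120C) by -1.45 ± 0.29 (SE, adjusted p = 0.0095) and ADE12 by -1.23. The purine and pyrimidine list as a whole, at a mean of -0.14, did not pass (adjusted p = 0.17). The other large differences downward were HPF1 at -1.47, SDT1 at -1.21, ODC2 at -0.96, the mitotic cyclin gene CLB1 at -0.76, COX20 at -0.75 and KGD2 at -0.64. Upward, SRO9 (0.70), PLB2 (0.63), AAP1 (0.62), MET32 (0.59), AXL2 (0.58), RPS14B (0.53), ARE2 (0.52), STP3 (0.51), DNF2 (0.51) and PAN1 (0.48) followed LYS2.

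Mitochondrial ribosome genes were lower in disomes than in cdc mutants in 67 of 71 cases (mean -0.26, adjusted p = 3.2e-10, adjusted p = 0.82 with an estimated correlation), and MRPL22 (-0.54) and MRPL16 (-0.50) fell singly. Oxidative phosphorylation was lower in 35 of 35 (mean -0.47, adjusted p = 6.6e-08, adjusted p = 0.82 with an estimated correlation), with ATP7 at -0.80 ± 0.25 and COX5B at -0.76 ± 0.28 (SE). Stress induced genes were lower in 69 of 77 (mean -0.43, adjusted p = 3.7e-06, adjusted p = 0.82 with an estimated correlation), with YRO2 at -1.54 ± 0.63 and HXK1 at -1.30 ± 0.58 (SE), and amino acid biosynthesis in 53 of 66 (mean -0.34, adjusted p = 9.5e-05, adjusted p = 0.82 with an estimated correlation). Adjusted over the list alone, 49 genes passed, 13 of them in amino acid biosynthesis and 10 in the mitochondrial ribosome, and 11 of 33 lists passed with the preset correlation. The count of 211 became 856 without cdc15-2, 14 without cdc23-1, 7 without cdc28-4 and 38 without replicate 2 of the disomes. It was 81 with Agilent's log ratios, 25 with genes on the extra chromosome kept and 351 with the array platform as a block.

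In the phosphate-limited chemostats, where growth rate is set by the dilution, disomes were again set against wt. The wt array shared no day with the disome arrays, so day of the array went with the group. ADE1 was higher by 3.36 ± 0.62 (SE), or 10.2-fold from the background model with its offset. This is no exact fold, since ADE1 was above background in 1 of 14 references and in neither channel of the wt array. With such references set to the array's lowest signal above background, the bound is at least 89.8-fold as the mean over 13 strains. In the lowest strain it is 48.7-fold. As in batch, ADE1 DNA was low in the reference strain, so the difference cannot be read as a response to the extra chromosomes. LYS2 was higher by 2.08 ± 0.43 (SE, adjusted p = 0.021). Its median signal was 354 in the disomes' references and 1526 in that of the cdc mutants. SPS100 (YHR139C), a spore wall gene, was lower by -2.16 ± 0.37 (SE, adjusted p = 0.0030) and YNL194C, which was named after its value was seen, by -1.56 ± 0.28 (SE, adjusted p = 0.0049). On the single wt array SPS100 itself read 2565 in the strain channel and 917 in its own wt reference. All 4 had their direction in 13 of 13 strains, and no other gene of 5765 passed. Stress induced genes were lower in 64 of 77 (mean -0.69, adjusted p = 1.1e-07, adjusted p = 0.89 with an estimated correlation), with HSP26 at -2.64 ± 0.91 and CTT1 at -2.51 ± 0.86 (SE). Ribosome biogenesis was higher in 103 of 123 (mean 0.20, adjusted p = 3.1e-06, adjusted p = 0.89 with an estimated correlation), with PWP1 at 0.78 ± 0.30 and UTP5 at 0.58 ± 0.22 (SE). In all 8 of 33 lists passed with the preset correlation, and 5 genes adjusted over the list alone. This contrast rests on 1 wt array, with which a permutation p cannot go below 0.067, and on 1 disome array with the dyes the other way round: without that array, of Dis XI and XVI, limma called 0 genes (189 unadjusted). Counts of the alternatives ran from 0 to 1513, the latter against the reference RNA without the wt array, and ribosome biogenesis turned to -0.14 with wt and YAC arrays as 1 control group.

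Disomes were compared with YAC strains, which carry extra DNA in an artificial chromosome, in the same chemostats. TRP1 (YDR007W), a tryptophan synthesis gene, was lower in disomes by -4.42 ± 0.48 (SE, adjusted p = 4.7e-08), LEU2 (YCL018W), a leucine synthesis gene, by -1.72 ± 0.35 (SE, adjusted p = 0.014) and the open reading frame YDR008C, which overlaps TRP1, by -0.75 ± 0.09 (SE, adjusted p = 7.2e-07). For TRP1 the difference lay mostly in the YAC strains: its median signal was 53995 there, 1301 in these disomes and 1463 on the wt array. Dis VIII, among these disomes, had low DNA of TRP1 (-6.01) and YDR008C (-5.92). LYS2 was higher by 2.00 ± 0.29 (SE, adjusted p = 2.1e-05) and ADE1 by 2.99 ± 0.42 (SE, adjusted p = 1.5e-05), each in 13 of 13 strains. For ADE1 this is no exact fold. It was above background in 1 of 6 YAC strains, YAC-7 (2.23, others 0.06 to 0.10), in 0 of 6 of their references and in 1 of 14 disome references. Without YAC-7 the difference was 3.35. YAC strains have no DNA array, so whether they lack ADE1, whose DNA was low in the wt reference, was not tested. YDL247W-A, at -0.48 ± 0.10 (SE, adjusted p = 0.014), completes the 6 genes past the threshold, and it and YDR008C were named after their values were seen.

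The proteasome list was higher in disomes than in YAC strains in 38 of 42 genes (mean 0.19, adjusted p = 4.6e-10, adjusted p = 0.61 with an estimated correlation), with RPN10 at 0.47 ± 0.15 and RPT5 at 0.45 ± 0.15 (SE). Its mean was higher in 14 of 14 disomes, also by permutation of the arrays (two-sided permutation p = 3.9e-04, adjusted permutation p = 0.0043). Mitochondrial chaperones were higher in 9 of 10 genes (mean 0.33, adjusted p = 7.7e-04, adjusted p = 0.59 with an estimated correlation, adjusted permutation p = 0.0021), with HSP60 at 0.76 ± 0.30 and HSP78 at 0.60 ± 0.31 (SE). Ribosome biogenesis was lower in 106 of 123 (mean -0.19, adjusted p = 9.2e-07, adjusted p = 0.91 with an estimated correlation, adjusted permutation p = 0.063), with EBP2 at -0.79 ± 0.36 and RRP14 at -0.73 ± 0.31 (SE). Cytosolic ribosomal proteins were lower in 107 genes (mean -0.13, adjusted p = 9.1e-04, adjusted p = 0.91 with an estimated correlation), and turned to 0.07 without a dye term. Permutation called 7 of 33 lists in all, and the other 5 were cytosolic chaperones at 0.26, the phosphate regulon at -0.25, G2/M cell cycle genes at -0.16, M/G1 genes at -0.21 and the strain markers at -0.47. Adjusted over the list alone, 12 genes passed, 6 of them proteasome genes, and 13 lists passed with the preset correlation. Dye orientation and day of the array went with the group. The permuted list means had the estimated dye effect subtracted. Their permutation p-values carry no error of that estimate, and cannot separate the karyotype from dye or day. The count of 6 became 943 without a dye term and 870 with the dye effect of the wt arrays subtracted in the chemostat arrays alone. It was 11 with each growth condition fitted alone, 3 without Dis XI and XVI and 15 without YAC-1c.

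YAC strains against wt asked whether carrying an artificial chromosome changed expression. What DNA the YACs carry is not given in the sources used here. TRP1 was higher by 4.27 ± 0.62 (SE, adjusted p = 1.1e-04) in 6 of 6 strains and YDR008C by 0.64. SPS100 was lower by -1.66 ± 0.32 (SE, adjusted p = 0.0078), SDP1 by -0.77, CMG1 by -0.71, OPI10 by -0.67, PFU1 by -0.54, AHC2 by -0.44, YKU70, of the DNA end-binding complex, by -0.43 and RRI1 by -0.37, each in 6 of 6, and YNL194C by -1.07. These 11 are all the genes past the threshold. All 11 rest on the 1 wt array, whose spread is taken from the other groups of the fit. For SPS100 that array read 2565 in the strain channel against 917 in its own wt reference. On the YAC arrays SPS100 read 0.59 in YAC-2, where the 5 others lay between -0.98 and -0.49. Ribosome biogenesis was higher in 121 of 123 genes (mean 0.39, adjusted p = 3.6e-25, adjusted p = 0.60 with an estimated correlation), with PWP1 at 0.76 ± 0.26 and NSR1 at 0.69 ± 0.27 (SE). Stress induced genes were lower in 72 of 77 (mean -0.57, adjusted p = 6.0e-09, adjusted p = 0.69 with an estimated correlation), with HSP26 at -1.98 ± 0.80 and GRE1 at -1.87 ± 0.86 (SE). Of 33 lists, 13 passed with the preset correlation, and 2 genes passed adjusted over the list alone. With 1 wt array a permutation p cannot go below 0.14, and the count of 11 was 18 without YAC-1c, 27 without YAC-2, 4 without YAC-7, 4 without wt replicate 4, 4 without background subtraction, and 0 in limma (275 unadjusted) with Agilent's log ratios.

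In the chemostats the cdc mutants differed from their wt in a single gene, the mitochondrial open reading frame Q0297, at -1.21 ± 0.23 (SE, adjusted p = 0.018), named after its value was seen. Stress induced genes were higher in 69 of 77 (mean 0.36, adjusted p = 2.0e-09, adjusted p = 0.69 with an estimated correlation), with CTT1, a catalase, at 1.21 ± 0.47 and TMA10 at 1.03 ± 0.47 (SE). G2/M cell cycle genes were higher in 18 of 18 (mean 0.20, adjusted p = 4.0e-08, adjusted p = 0.66 with an estimated correlation), with CLB1 at 0.48 ± 0.25 and MOB1 at 0.32 ± 0.11 (SE). Ribosome biogenesis was lower in 103 of 123 (mean -0.11, adjusted p = 1.1e-07, adjusted p = 0.81 with an estimated correlation), with SOF1 at -0.37 ± 0.17 and SSF1 at -0.35 ± 0.19 (SE). The preset correlation passed 15 of 33 lists, and 5 genes passed adjusted over the list alone. Permutation of 3 arrays cannot give a p below 0.25, and limma called 0 genes without cdc23-1 (319 unadjusted), without cdc28-4 (127) and without wt replicate 4 (243), and 2 without cdc15-2.

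The difference between the disome response in batch and in the chemostats was tested directly. Its chemostat side sets disome arrays against a wt array of another day. SPS100 had a response higher in batch by 2.35 ± 0.44 (SE, adjusted p = 0.019) and YNL194C by 1.74 ± 0.34 (SE, adjusted p = 0.020), and no other gene of 5765 passed. In batch SPS100 was above background in 1 of 37 disome references and in neither channel on 3 of the 4 wt arrays, so a fall in batch could not have been seen and the difference rests on the chemostat arrays. Stress induced genes had a higher response in batch in 71 of 77 (mean 1.04, adjusted p = 2.0e-11, adjusted p = 0.84 with an estimated correlation), with the small heat shock genes HSP26 at 3.62 ± 1.09 and HSP12 at 3.27 ± 1.38 (SE). Ribosome biogenesis had a lower one in 104 of 123 (mean -0.30, adjusted p = 4.3e-09, adjusted p = 0.84 with an estimated correlation), with PWP1 at -1.05 ± 0.36 and DBP2 at -0.78 ± 0.48 (SE). Adjusted over the list alone, 5 genes passed, and 11 of 33 lists passed with the preset correlation. The single chemostat wt array enters every value here, and limma called 0 genes without Dis XI and XVI (170 unadjusted) or with Agilent's log ratios (541 unadjusted). With no dye term it called 249.

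Across all 8 comparisons, 97 of 264 list tests passed with the preset correlation and none with an estimated one (lowest adjusted p = 0.594) or with fry, a rotation test (lowest adjusted p = 0.152). The mean, median and test of a list had the same sign in every test that passed. PDR5, CLN2, HIS3, CDC15, CDC23 and CDC28, which the labels or media name, passed in no comparison.

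Taken strain by strain, the number of genes off the extra chromosome that changed in batch had a median of 694 over 19 strains. Dis V had 1245, its single array being assumed to vary like the other strains. Dis IV had 2770 and the 2 isolates of Dis I had 25 and 19. Isolates could also differ widely: those of Dis II had 1166 and 201, and those of Dis X 267 and 160. The 2 isolates of each karyotype were measured against different wt reference RNAs. LYS2 and ADE1 rose in 17 of 17 strains measured and HXT6 and HXT7 in 17 of 18, while SAT4 fell in 16 of 19 and VAC17 in 15 of 19. Every strain was set against the same 4 wt arrays, so such recurrence is not independent between strains. With only 1 array per strain the median was 74 without replicate 1 and 63 without replicate 2, the lone array being assumed to vary like the other groups.

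Response size was related to the number of measured genes on the extra chromosomes, in 6 relations. The SD of log2 over genes off the extra chromosome rose with gene number in batch (r = 0.65, permutation p = 0.0018, adjusted 0.011, rho = 0.65, permutation p = 0.0034, 19 strains), and r was 0.77 without the 2 strains farthest from the median gene number. Those 2 were Dis XI and XV (SD 0.34) and Dis XI and XVI (SD 0.26), while Dis IV, with 754 genes and the SD of 0.57, stayed in. Isolates of the same karyotype counted as separate strains. Within the 11 strains measured against the second wt reference, r was 0.67 (permutation p = 0.020) and 0.63 without the 2 farthest of them (permutation p = 0.069), and the first held too few strains. The score of stress induced genes had r = 0.49 in batch (permutation p = 0.030, adjusted 0.090, rho = 0.57, permutation p = 0.012), 0.68 without those 2 strains and 0.44 within the second reference (permutation p = 0.19). Without strains with several extra chromosomes it was 0.72 (permutation p = 0.0018), and 0.39 when the 2 farthest of the remaining strains were left out too (permutation p = 0.17). The ribosome biogenesis score had r = -0.31 (permutation p = 0.20, adjusted 0.29, rho = -0.28, permutation p = 0.25), and -0.36 within the second reference (permutation p = 0.27). It was -0.58 without those 2 strains (permutation p = 0.015) and -0.65 without strains with several extra chromosomes (permutation p = 0.0059), but -0.35 when the 2 farthest of the remaining strains were left out too (permutation p = 0.22). In the chemostats r was 0.49 for the SD (permutation p = 0.075, rho = 0.39), -0.25 for stress induced genes (permutation p = 0.38, rho = -0.23) and 0.21 for ribosome biogenesis (permutation p = 0.47, rho = 0.13) over 14 strains, all two-sided.

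**Figure D4:**
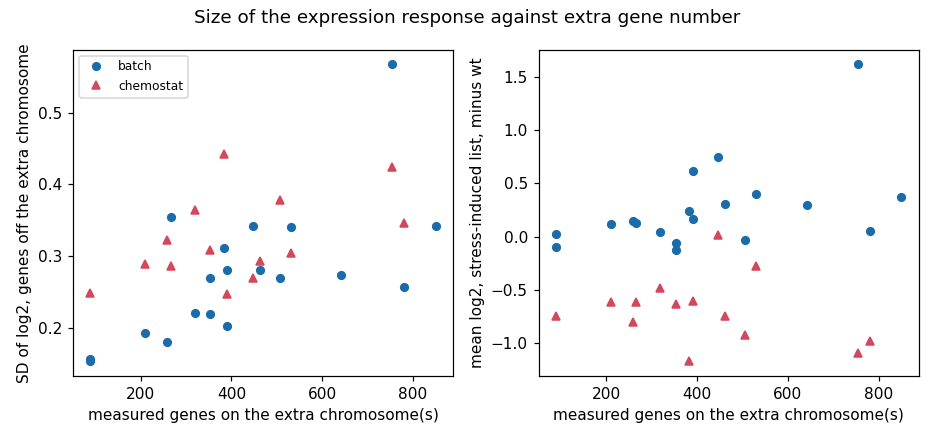
SD of log2 over genes off the extra chromosome (left) and the mean log2 of stress induced genes minus wt (right) against the number of measured genes on the extra chromosomes, 1 point per strain, in batch and in the chemostats. In batch r is 0.65 on the left and 0.49 on the right.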

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

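The test of the same genes in RNA and DNA, the test of the DNA level of HXT6 and HXT7, both tests of the PDR5 arrays and the value of the brightest class for batch minus chemostat were chosen after the result was seen.

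The first pattern is that RNA of genes on the extra chromosome lay below the DNA gain of the same strain, by a mean of -0.34 over 19 batch strains. Genes that do not respond at all are too few to carry it: 6.21% of 1144 bright genes, and 11.6% of all 4700, had a mean log2 below 0.2. That background handling compresses the ratios of dim spots was to be excluded if the brightest of 4 classes of genes stayed more than 0.1 below DNA, and it read -0.12 (SD 0.10, exact sign-flip p = 5.7e-05). That bound was poorly set, since it compared bright genes with the DNA median of all genes (0.94) when DNA of the bright genes themselves read 0.89, and -0.12 is within 2 standard errors of it. Compared gene for gene with Agilent's log ratios, RNA minus DNA in the brightest class was -0.0075 (exact sign-flip p = 0.78, below in 9 of 19 strains), and with the background model used here -0.06 (exact sign-flip p = 0.020), so that background handling is a candidate explanation for most of the gap and a reduced response of some genes stays open.

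The second pattern is that 5 of the 11 DNA arrays labelled pdr5 did not show PDR5 lost. Exchanged dye channels are excluded, because the labelled chromosome on those arrays read at least 0.902. A reference that also lacks PDR5 is a candidate explanation: its PDR5 signal was at most 0.188% of the array's median reference signal there, against at least 12.3% on the 6 other arrays. On 4 of the 5 the strain's own PDR5 signal was as low as the reference's, and on the array of Dis XIII it was not (540 against 2.39). Whether that strain keeps PDR5 or another DNA was hybridised was not tested.

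The third pattern is that HXT6 and HXT7 RNA was raised in disomes, with a mean of 2.65 ± 1.40 (SD, 18 strains) in batch and 2.36 ± 1.41 (SD, 13 strains) in the chemostats. It was 0.38 in batch wt (4 arrays), -0.42 ± 0.51 in YAC strains (SD, 6 arrays) and, in cdc mutants against their own wt, 2.25 ± 2.11 in batch and 0.58 ± 0.23 in the chemostats (SD, 3 arrays each). The single chemostat wt array read 0.70. Fewer copies of the locus in the reference might contribute: the median DNA log2 was 0.62 in strains without an extra chromosome IV, but wt against itself read 0.38, which leaves this open. DNA at the locus and batch RNA had r = 0.11 over 18 strains (permutation p = 0.67, rho = 0.15, permutation p = 0.55, r = 0.30 without 2 strains), and this many strains cannot exclude a relation. A biological response to the extra chromosomes stays untested.

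Single YAC arrays stood apart from the rest of the 6, and 7 of 42 groups of 4 to 10 samples tested this way did so, where chance gives about 1 in 20. YAC-7 had TRP1 at 2.21 (others 4.48 to 5.02). YAC-7 had CDC28 at -0.47 (others -0.07 to 0.15). YAC-7 also had ADE1 at 2.23 (others 0.06 to 0.10) and LYS2 at 0.49 (others -0.13 to 0.06). YAC-2 had YKU70 at -0.16 (others -0.54 to -0.40). YAC-2 had SPS100 at 0.59 (others -0.98 to -0.49). YAC-1c had PDR5 at -3.04 (others -0.39 to -0.05).

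Some effects differed between groups under a direct test. Expression on the extra chromosome differed between batch and chemostat by -0.054, which turned to 0.020 with Agilent's log ratios and to 0.012 in the brightest class of genes. Disomes and cdc mutants, measured against different references, differed in 211 genes in batch, and in 7 without cdc28-4. The genes that follow rest on 1 chemostat wt array, and in batch SPS100 was above background in 1 of 37 disome references. The disome response of SPS100 differed between batch and chemostat by 2.35 and that of YNL194C by 1.74, and limma called 0 genes there with Agilent's log ratios (541 unadjusted) and without Dis XI and XVI (170 unadjusted).

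Other signals lay outside the comparisons. On the DNA array of Dis VIII, XV, and s-YAC, a window of 20 genes on chromosome III, from YCL068C to EMC1, read 0.90, where the highest window of the wt array read 0.21, which 26 arrays exceeded. On the same array a window on the labelled chromosome VIII, from SOD2 to VMA16, read -0.15. On the DNA array of Dis X (A6869), a window on chromosome IV from SKP1 to PAL1 read 0.54. Mitochondrial genes on the array of Dis VIII, XV, and s-YAC had a median DNA log2 of 3.21 over 23 genes, where the wt array read -0.71, Dis IV CLN2-3HA 2.65, Tris V -2.65 and Dis XIII CLN2-3HA -3.22 (SD 1.18 over the DNA arrays). On the trisome arrays the reference's ADE1 signal had a median of 34.7% of the array's median, against a median of 1.14% on the 37 other arrays.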

How the results depend on the processing

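Fry, the brightest of 4 classes of genes, the gene's mean in the other disomes subtracted, and the fits without the 2 strains farthest from the median gene number, without URA5, URA2 and ADE16, or without YAC-1c, YAC-2 or YAC-7 were chosen after the result was seen. Of 270 alternatives for the comparisons, 193 left the value in place, 68 moved it, 5 reversed it and 4 strengthened it. Of 2523 for single genes and described lists, 2102 left the call in place, 403 lost it, 9 reversed and 9 gained one. Over all lists, 4686 alternatives kept the call in 3991, with 147 gained, 241 lost, 37 reversed (14 lists in 6 comparisons) and 270 with a sign change past the threshold in neither. Single genes that passed neither way and changed sign, 70 cases in 6 genes with a largest size of 0.36, count as in place. Disome against wt in batch called 2 genes, the same 2, under every alternative counted here, with the replicate block (110 unadjusted) and with scan day as a block (83 unadjusted) too. Within the first wt reference alone (3 strains, 1 wt array) neither was tested, and limma called 0 (84 unadjusted). The cause of each change that follows was not tested unless named.

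Normexp for DNA gave a disome mean of 1.23 and 1 gain beyond the labels. Agilent's log ratios and the deposited values gave, each, 76 genes for cdc mutants against wt in batch, 81 for disome against cdc, 2 for disome against wt in the chemostats, 0 for YAC against wt (limma, 275 unadjusted), 0 for the batch against chemostat response (limma, 541 and 542 unadjusted), 4 chemostat lists on the extra chromosome, and 0.020 for batch minus chemostat on the extra chromosome, reversed. The brightest class of genes gave 0.012 there, also reversed. Without background subtraction YAC against wt had 4. With genes on the extra chromosome kept, the counts were 4 for cdc, 25 for disome against cdc, 2 for chemostat disome against wt, 3 for YAC against wt, and a median of 1502 per strain, which includes those genes by construction. Leaving out strains with several extra chromosomes, in the chemostats Dis XI and XVI alone and with it the only disome array with the strain in Cy5, gave 0 for chemostat disome against wt (limma, 180 unadjusted), 4 for YAC against wt, 0 for chemostat cdc (176 unadjusted), 0 for the response difference (147 unadjusted), 426.5 per strain, and correlations with gene number of 0.72 for stress induced genes and -0.65 for ribosome biogenesis, which were 0.39 (permutation p = 0.17) and -0.35 (permutation p = 0.22) without the 2 farthest of the remaining strains. With all strains but the 2 farthest they were 0.68 and -0.58, and in the chemostats 0.21 and -0.11, reversed with neither past the threshold. Each growth condition fitted alone gave 1, 11 and 1 for disome against wt, disome against YAC and YAC against wt in the chemostats, and 0 for cdc (limma, 407 unadjusted). The platform as a block gave 351 for disome against cdc, 4 for YAC against wt and 0 for chemostat cdc (limma, 284 unadjusted). Scan day as a random block gave 0 for chemostat cdc (limma, 202 unadjusted), and all arrays with the strain as a random block 0 for batch cdc (limma, 507 unadjusted).

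Without a dye term the chemostat counts were 24 for disome against wt, 943 for disome against YAC and 21 for cdc, and 249 for the response difference. With the dye effect of the wt arrays subtracted, chemostat arrays alone, they were 2, 870, 1 for YAC against wt and 2 for cdc. These 2 settings carry no error for the dye effect, by construction. Against the reference RNA without the wt array, disomes had 1513 genes. Without the array of Dis XI and XVI, disome against wt had 0 (limma, 189 unadjusted), disome against YAC 3 and the response difference 0 (limma, 170 unadjusted). An estimated correlation and fry each called 0 of 264 list tests, where camera with the preset correlation called 97. Of the lists described in the report, those that reversed were ribosome biogenesis in batch disomes (0.051 with the reference RNA as a block, and -0.14 to 0.019 leaving out 1 wt array, above 0 without wt replicates 1 and 4) and in chemostat disomes (-0.14 with wt and YAC arrays as 1 control group), and ribosomal proteins against YAC (0.066 without a dye term). With the gene's mean in the other disomes subtracted, on the extra chromosome ribosomal proteins (0.024) and ribosome biogenesis (0.11) reversed in batch and stress induced genes (0.19) in the chemostats, and without URA5, URA2 and ADE16 purine and pyrimidine synthesis in the chemostats (0.21). Without YAC-1c disome against YAC had 15 genes and YAC against wt 18, and the latter had 27 without YAC-2 and 4 without YAC-7. Leaving out 1 replicate, wt array or mutant, counts ran from 1 (without cdc23-1) to 1103 (without cdc15-2) for batch cdc, 7 (without cdc28-4) to 856 (without cdc15-2) for disome against cdc, 4 (without wt replicate 4) to 11 for YAC against wt, 0 (without wt replicate 4, limma, 243 unadjusted) to 2 (without cdc15-2) for chemostat cdc, and 63 to 74 for the per-strain median, which then has 1 array per strain. The brightest probe was not run, as each gene has 1 probe sequence, and a fixed day block could not be estimated in the joint fit. Signal over background limits the dim genes, and on the batch array with the fewest 85.9% of genes were above it.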

Other observations

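The test of the lysine genes was written before its result was seen, although the pattern had been noticed in these data, and the genes in the first 2 paragraphs were chosen after their values were seen.

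DNA of 6 genes on a gained chromosome was more than 3 below the reference on the log2 scale, on 12 disome arrays in all: URA5, URA2, ADE16, the methionine and sulfur genes MET12 and MET14, and YHR218W. URA5 in Dis XIII was at -5.63 in batch (2 arrays) and -5.22 in the chemostat (1 array), against 0.07 in disomes without an extra chromosome XIII, and its DNA was at -4.36 or lower on 3 of 4 arrays. URA2 in Dis X was at -5.23 in batch (4 arrays, with strain signal above background on 2, so no exact size) and -5.31 in the chemostat. Its DNA was at most -3.33 on 3 of 3 arrays. ADE16 in Dis XII was at -3.11 in batch (2 arrays) and -3.51 in the chemostat, with DNA at most -4.07 on 3 of 3 arrays, all of these without strain signal above background. MET12 in Dis XVI and Dis XI and XVI was at -2.04 ± 0.11 in batch (SD, 4 arrays) and -1.78 in the chemostats (2 arrays), against -0.08 in batch without an extra chromosome XVI, with DNA at -2.37 or lower on 3 of 3 arrays. MET14 in Dis XI and XV had DNA at -3.25 and batch RNA at -1.37 and -1.56, not above background, while its DNA was at 0.91 and 0.94 on 2 other arrays with an extra chromosome XI. YHR218W was at -3.55 on the DNA array of Dis VIII, XV, and s-YAC, which has no RNA array. Genes on chromosomes without a gain were as low on that array, among them YFL066C at -3.79 and YBL112C at -3.72. The fall of YHR218W was thus not particular to the gained chromosome. ADE1, by contrast, was low in the wt reference: its RNA was at -0.02 in batch in Dis I (4 arrays) and at 3.17 ± 0.53 (SD, 33 arrays) in the other disomes, and its DNA gave at most 16.3 in either channel on the 3 disome arrays of chromosome I alone, where the array medians were at least 969, but 740 against 9.59 in the reference on that of Dis I, VI, and XIII.

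Strain by strain in batch, further genes recurred, all against the same wt arrays. The lysine genes LYS9 and LYS20 rose in 14 of 17 and 13 of 18 strains, and CTP1, the mitochondrial citrate transporter gene, in 13 of 17. The mitotic cyclin gene CLB2 fell in 13 of 17, and the acid phosphatase genes PHO11 and PHO12 in 11 of 17 each. Isolates of the same karyotype correlated across genes with r = 0.55 for Dis I, 0.48 for Dis II and 0.56 for Dis X, where the median of 171 pairs of disome strains was 0.33 and the highest 0.85, and genes are not independent replicates.

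A hypothesis is that the wt reference has little LYS2 RNA and that the other lysine genes follow LYS2. LYS2 DNA was at -0.05 (median of disomes), so the gene itself was present in both. In the chemostats 6 other lysine genes were higher in disomes than in YAC strains by 0.902 (exact permutation p = 5.2e-05, two-sided, 13 of 14 disomes above the highest YAC array), where LYS2 in YAC strains was at 0.04. In batch they were higher than in wt by 0.57 (exact permutation p = 0.0096, two-sided, 17 of 19 disomes above the highest wt array). Of the 6, LYS20 was at 0.65 ± 0.26 in batch and 1.19 ± 0.40 in the chemostats (SE), and LYS21 at 0.19 ± 0.19 and 0.94 ± 0.33. In the cdc mutants against their own wt, the 6 genes were at 0.34 ± 0.85 in batch (SD, 3 arrays), with LYS2 at 0.33. In their chemostats the 6 genes were at 0.03 ± 0.18 (SD, 3 arrays). The batch mean of the mutants thus came near 0.42, that of the disomes, without a comparable LYS2 ratio, but with a wide spread. The result in the disomes goes with the hypothesis, but dye orientation and day of the array went with the group in the chemostats. The estimated dye effect was subtracted there first, and the permutation p carries no error of that estimate. The raised ADE1 and LYS2 may also mark another difference in strain background.

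Samples were also divided into other groups of the same sizes. For cdc mutants against wt in batch, 1 of 35 splits, the real one, gave as many as 229 genes, and the highest other split gave 22. The mutants shared 1 reference RNA, and a chance deviation of that RNA would also set the real split apart. Chance is therefore not called excluded. The splits cannot separate the mutations from the scan day and the reference strain, which the mutants shared with no batch array of wt or disomes, so this holds for disome against cdc too. The count of 229 was 1 without cdc23-1 and 2 without cdc28-4. For disome against cdc the share of splits at 211 genes or more, 3 of 100 with the real one, was below the limit set beforehand. Another split gave more genes than the real one, at 449, so chance is not called excluded here. That split kept cdc23-1 and cdc28-4 and put a Dis XV in place of cdc15-2, which points to a structure of the samples. The count of 211 was 14 without cdc23-1 and 7 without cdc28-4. For disome against wt in batch chance could not be excluded for the count of 2, with 5 of 100 splits as high. The highest other split gave 102 genes and set Dis IV, Dis XV, Dis XI and XV and 1 wt array against the rest, again a structure of the samples. For disome against YAC chance could not be excluded for the count of 6, with 8 of 100 splits as high and the highest other at 72, which points to such a structure too.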
